A study of Homo sapiens with 112 samples.

How the data were processed

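The series holds mRNA levels of 112 arrays from established human breast cell lines, each with 54675 probe sets. The values are on a log2 scale and had been background corrected, normalized between arrays and summarized per probe set with GCRMA by the authors before they were deposited, as the submitters' processing notes and the values show. The GCRMA version, the chip definition and the array batches are not stated, and no raw intensities were used. All columns were used (columns not used, 0). Array medians were checked and ranged from 3.06 to 3.38, and 37.9% to 40.6% of probe sets lay above 4. The 3′ minus 5′ difference of the ACTB control probe sets ranged from 0.50 to 1.73 over the arrays. Arrays give no count depth, so precision rests on the number of arrays.

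Probe sets were assigned to genes with the supplied probe annotation. Of the probe sets, 41097 belonged to 1 gene, 1801 to several genes and 11777 to none, and 62 were control probe sets. The 19775 genes with a probe set of their own were each represented by the probe set with the highest mean over the arrays of the fit. A gene was tested when its log2 value was above 4 in at least as many arrays as the smallest group compared. Gene positions are those of GRCh38.

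Arrays were grouped by their labels into 72 groups. Linear models were fitted with limma 3.58.1 in R 4.3.3, one for MCF7, one for MB231, one for the untreated arrays of both lines, one for the BT474 and BT474EI arrays and one for 7 replicated panel lines. Each treated arm was compared with the control of its own line and set, and the effect over both sets is the mean of the 2 effects. The difference between the sets was tested as an interaction, and so was the difference of the control effect between the lines, in a fit of the control and untreated arrays of both. Moderated tests were adjusted with the Benjamini-Hochberg method, and a gene was called changed at an adjusted p threshold of 0.05. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between arrays. The test of 7 lines used 16 arrays, 1 fewer than the plan had counted.

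Before the data were examined, 24 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Of 533 listed entries, 493 matched a gene with a probe set of its own. The lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation as an alternative, and adjusted over all 289 tests. Of these tests, 107 passed with the preset and 21 with the estimated correlation. The lists of microRNA targets hold reported targets and were written from general knowledge. Named genes were ESR1, then the 6 largest rises and 6 largest falls among called genes whose treated arrays all lay above or below their controls in each set, then up to 4 members of each list with the smallest adjusted p. For the test of 7 lines they were the 10 genes with the largest spread between lines. PGR, GREB1 and TFF1 in the ESR1 siRNA comparison, PGR, TRPS1, PRUNE1, ZBTB37, FILIP1L, DPY19L3 and HECTD2 in the mimic comparison, and PRUNE1, FILIP1L and TRPS1 in the inhibitor comparison lay outside the rule and were chosen after their values were seen.

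Levels and relations across the panel used 47 lines, after 9 labels that repeat or vary another label were left out, with the mean of the arrays of a label. Pearson and Spearman correlations were tested with 100000 permutations, or with every ordering where a cluster had fewer than 10 lines, and adjusted over the 16 relations. Lines were split into clusters where a gap in a gene's levels exceeded 0.25 of its range with at least 3 lines on each side, and a cluster needed at least 6 lines. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

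The alternatives were quantile normalization, median centring, no filter and a filter above 6, the median of a gene's probe sets, a fit of only the groups compared, a trended robust prior, a replicate block, other ESR1 probe sets, an estimated correlation, label variants kept, the panel without AU565, KPL1 and MDA435, and each array left out in turn. Alternatives added after seeing the data were the exchange of the control arms in MCF7, BT474 from replicate 1 alone in its comparison and across the panel, and a test of the lines without the BT474 arrays, alone or with the BT474EI arrays. The mimic and inhibitor arms were also compared with the untreated arrays, where 2628 and 3797 genes passed. This comparison was added after seeing the data too. Other splits of the same arrays were counted, up to 100 per comparison, and for the difference between sets also with the mean effect over both sets removed from each gene.

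The methods were tested on simulated data with 200 changed genes of log2 size 0.5, 1 or 2. Over both sets, 74.6%, 94.0% and 100% of these genes were recovered in the ESR1 siRNA design, 74.6%, 97.0% and 100% in the mimic design and 83.6%, 95.5% and 100% in the inhibitor design. In the BT474 design 0%, 5.97% and 45.5% were recovered, so small differences there are not detectable. The test of 7 lines recovered 78.5% of 200 genes shifted by 3 in 1 line. Of all calls in these simulations, 2.32% to 9.03% were unchanged genes. The permutation test found 5% of 40 simulated pairs with no relation, 60% with r = 0.3 and 100% with r = 0.7.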

Results

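The series measured mRNA levels in human breast cell lines with oligonucleotide arrays of 54675 probe sets, and 112 arrays were deposited. Of these, 65 arrays profiled lines with no treatment stated, under 56 labels. Of these labels, 49 had 1 array, 5 had 2 arrays, and BT474 and BT474EI had 3 arrays each. The other 47 arrays came from treatment experiments, with 29 arrays of MCF7 and 18 of MB231. MCF7 is an estrogen receptor positive line that grows as epithelial cells, and MB231 is taken here as MDA-MB-231, a mesenchymal line without the receptor. Each experiment was run as 2 sets, one labelled 72 h and one with no time stated. The MCF7 arms were untreated, control, mimic, siRNA control and ESR1 siRNA, and the MB231 arms were untreated, control and inhibitor. Each arm had 3 arrays per set, except ESR1 siRNA in the set with no time stated, which had 2. In common use a mimic is a synthetic copy of a microRNA and an inhibitor an oligonucleotide that blocks one, but the labels name no microRNA. The median log2 value per array ranged from 3.06 to 3.38, and 37.9% to 40.6% of probe sets lay above a log2 value of 4. With arrays, the number of replicates limits the precision.

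The comparison of ESR1 siRNA with siRNA control in MCF7 asks which genes depend on ESR1, which encodes estrogen receptor alpha. ESR1 mRNA (gene identifier 2099, chromosome 6, 151656672 to 152129619 in GRCh38) fell by 1.74 ± 0.08 on the log2 scale (SE, 5 treated and 6 control arrays). The log2 difference was -1.98 in the set with no time stated and -1.49 at 72 h. It fell by 1.00 with the median of all ESR1 probe sets, and passed. Of 33 measured genes listed as induced by estrogen, 31 fell, 0 rose and 2 did not pass, and 32 fell when adjusted over the list alone. They included MYB, a transcription factor, at -2.01 ± 0.08, the chemokine gene CXCL12 at -2.41 ± 0.10, and PGR, the progesterone receptor gene, at -2.25 ± 0.13. GREB1, an estrogen-responsive growth gene, fell by 1.27 ± 0.10. TFF1, a secreted trefoil peptide gene and a common marker of receptor activity, fell by 0.36 ± 0.05, with -0.06 in the set with no time stated (adjusted p = 0.67) and -0.67 at 72 h. Of 13 genes listed as repressed by estrogen, 12 rose, also when adjusted over the list alone. PSCA, a surface antigen gene, rose by 1.93 ± 0.11, the stress gene TP53INP1 by 1.50 ± 0.09, EFNA1, an ephrin ligand gene, by 0.75 ± 0.06, and CCNG2, a cyclin gene linked to cell cycle arrest, by 0.78 ± 0.07. With the median of all its probe sets, TP53INP1 rose by only 0.06 and did not pass, and CCNG2 rose by 1.46. Against the control arrays of the mimic arm, TP53INP1 rose by 0.77 and CCNG2 by 0.47. Both lists passed with an estimated correlation as well, at adjusted p = 0.000673 and 0.00339.

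Here and below, the largest rises and falls are ranked only among called genes whose arrays all lay above, or all below, their controls. Among the 6 largest rises after ESR1 siRNA were VAT1L at 3.53 ± 0.41, TNS3, a focal adhesion gene, at 3.35 ± 0.25, LOXL2, a collagen cross-linking enzyme gene, at 3.19 ± 0.39, and SNAI2, a repressor of epithelial genes, at 2.89 ± 0.26. TNS3 rose by 0.74 in the set with no time stated and by 5.96 at 72 h. SALL4 and RAB26 rose by 2.57 and 2.49. The 6 largest falls were SYBU at -3.30 ± 0.17, LINC01016 at -3.15 ± 0.17, LINC01588 at -2.86 ± 0.28, RUBCNL at -2.74 ± 0.17, RBM24 at -2.67 ± 0.08 and RAMP3, which encodes a receptor activity-modifying protein, at -2.62 ± 0.16. TNS3 rose by 1.67 with the median of probe sets, and under that setting LINC01016 measured -1.11, LINC01588 -1.30 and RUBCNL -1.60. LINC01588 measured -0.28 and did not pass when only the groups compared entered the fit, where another of its probe sets was used. Genes of DNA replication and the G1/S step fell in 15 of 27 cases and rose in 1, with 18 falls and 1 rise when adjusted over the list alone. GINS1, a replication complex gene, measured -0.00 in the set with no time stated and -1.05 at 72 h. Other members ran the other way, with the cyclin gene CCNE2 at -0.94 and 0.22 and the replication genes CDC45 at -0.62 and -0.09 and MCM6 at -0.54 and -0.11. Mitotic genes fell in 10 of 28 cases and rose in 0, with 12 falls and 1 rise when adjusted over the list alone. The G1/S and mitotic shifts did not pass with an estimated correlation, at adjusted p = 0.0831 and 0.349. ERBB2, which encodes the HER2 receptor, rose by 0.62 ± 0.10. In the limma fit, 3577 of 10839 genes changed, 2019 higher and 1558 lower, and 272 of them changed at least 2-fold. Rises made up 56.4% of the changed genes as deposited and 47.4% after quantile normalization. Against the control arrays of the mimic arm 1264 genes rose and 1911 fell, and 2252 of the 3577 genes passed in the same direction. In the set with no time stated 1720 genes passed and at 72 h 4317, but 266 in the former when only the groups compared entered the fit.

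**Figure D1:**
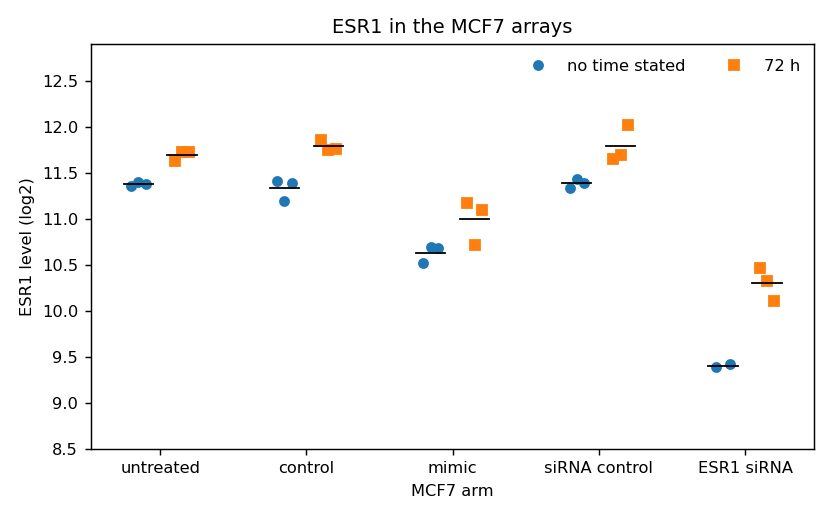
ESR1 level in log2 units (the probe set with the highest mean) in each MCF7 array, by arm, with circles for the set with no time stated, squares for 72 h and lines for arm means. The mimic arrays averaged 10.63 and 11.00, below the control arrays at 11.33 and 11.79, and the ESR1 siRNA arrays averaged 9.40 and 10.30, below the siRNA control arrays at 11.39 and 11.79.

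The comparison of mimic with control in MCF7 asks what the mimic changes. ESR1 fell by 0.74 ± 0.08 (SE, 6 treated and 6 control arrays), with a log2 difference of -0.70 in the set with no time stated and -0.79 at 72 h. The difference was -0.77 against the siRNA control arrays and -0.72 against the untreated arrays. With the median of all ESR1 probe sets it was -0.41 and did not pass. CDKN1B, which encodes the cell cycle inhibitor p27 (gene identifier 1027, chromosome 12, 12717368 to 12722369), fell by 0.86 ± 0.06, with -0.80 against the siRNA control arrays and -0.76 against the untreated arrays. Of 27 genes reported as targets of miR-221 and miR-222, the list that holds CDKN1B and ESR1, 16 fell, 0 rose and 11 did not pass. Adjusted over the list alone, 17 fell and 1 rose. RALGAPA1, a GTPase-activating protein gene, fell by 1.12 ± 0.08, and GJA1, which encodes connexin 43, measured -0.02 in the set with no time stated and -2.54 at 72 h. DDIT4, a stress-induced mTOR inhibitor gene, fell by 0.75 ± 0.05, but measured -0.22 against the siRNA control arrays and 0.04 against the untreated arrays. The list shift did not pass with an estimated correlation (adjusted p = 0.0753). Of the members, 14 fell and 1 rose against the siRNA control arrays, and 12 fell and 3 rose against the untreated arrays.

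Among the genes listed as induced by estrogen, 20 of 33 fell and 1 rose with the mimic, with 24 falls and 2 rises when adjusted over the list alone (adjusted p = 0.0502 with an estimated correlation). MYB measured -0.94 ± 0.07, FHL2, a LIM domain cofactor gene, -1.42 ± 0.11, the receptor kinase gene RET -0.83 ± 0.09 and PGR -0.84 ± 0.12. PGR measured -0.50 against the siRNA control arrays. These means hide a difference between sets, with larger falls at 72 h. The difference, 72 h minus no time stated, was -2.01 ± 0.22 for FHL2, -1.12 ± 0.18 for RET and -0.67 ± 0.15 for MYB. PGR measured -0.55 with no time stated and -1.13 at 72 h. MYB measured -0.58 and PGR -1.34 with the median of probe sets. Genes listed as repressed by estrogen did not all rise with the mimic, since CCNG2 fell by 0.31 ± 0.07 and NDRG1 by 0.55 ± 0.09. Luminal markers fell in 10 of 17 cases and rose in 0, with 11 falls when adjusted over the list alone (adjusted p = 0.0502 with an estimated correlation). TRPS1, a luminal transcription factor gene, fell by 0.36 ± 0.09 but did not pass against the siRNA control arrays (adjusted p = 0.0937). Basal and myoepithelial markers fell in 6 of 9 cases, also when adjusted over the list alone. CAV1 and CAV2, which encode caveolins, measured -1.30 ± 0.06 and -0.89 ± 0.04. Both fell more at 72 h than with no time stated, by a difference of -2.05 ± 0.11 and -1.18 ± 0.09. Genes of sterol and lipid synthesis fell in 17 of 20 cases, also when adjusted over the list alone, with INSIG1, a sterol sensor gene, at -0.39 ± 0.05, or -0.21 against the siRNA control arrays. The basal and sterol shifts passed with an estimated correlation, at adjusted p = 0.0432 and 0.0310. Genes of hypoxia and glycolysis fell in 15 of 22 cases, or 20 when adjusted over the list alone (adjusted p = 0.0571 with an estimated correlation). The control arm had itself raised 15 of those 22 genes over untreated cells. Against the siRNA control arrays, 6 luminal, 3 basal, 5 sterol and 2 hypoxia genes fell. Against the untreated arrays 7 luminal, 4 basal, 11 sterol and 1 hypoxia genes fell, while 1 sterol and 2 hypoxia genes rose. Genes of the p53 response rose in 6 of 19 cases and fell in 1, with 8 rises and 2 falls when adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.53 ± 0.05, and more at 72 h, by a difference between sets of 0.53 ± 0.11.

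Changes with the mimic were ranked among called genes whose mimic arrays all lay above, or all below, their controls in each set. Among these genes the largest rises were those of CYP1A1, a cytochrome P450 gene of xenobiotic metabolism, at 2.81 ± 0.44, PALM3 at 1.49 ± 0.31 and RGS16, a regulator of G protein signalling, at 1.40 ± 0.28. RGS16 did not pass against the siRNA control arrays, where it measured 0.82. The largest falls were those of CYP26B1, which degrades retinoic acid, at -3.60 ± 0.26, RUBCNL at -2.49 ± 0.16, LINC01016 at -2.40 ± 0.16 and ANXA1, which encodes annexin A1, at -2.33 ± 0.13. Their size and order depend on the control arm and on the probe sets. Against the siRNA control arrays CYP26B1 measured -1.85, RUBCNL -1.53, LINC01016 -2.29 and ANXA1 -1.60, and with the median of probe sets -1.80, -1.38, -0.45 and -1.15. ANXA1 measured -0.45 in the set with no time stated and -4.22 at 72 h. In the limma fit, 2223 of 10839 genes changed, 524 higher and 1699 lower, and 113 changed at least 2-fold. In the set with no time stated 168 genes passed, or 36 when only the groups compared entered the fit, and at 72 h 2709 passed. Rises made up 23.6% of the changed genes as deposited and 52.7% after quantile normalization. Against the siRNA control arrays 790 genes rose and 879 fell, and 986 of the 2223 genes passed in the same direction. In the set with no time stated the 3′ minus 5′ difference of ACTB, a sign of RNA quality, was 1.40 to 1.48 in the mimic arrays and 1.27 to 1.40 in the control arrays. At 72 h it was 1.31 to 1.61 against 1.14 to 1.36, and its effect was not tested in either set.

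The comparison of inhibitor with control in MB231 asks what the inhibitor changes in cells that lack ESR1, whose level stayed near the background of the arrays. CDKN1B rose by 0.93 ± 0.06 (SE, 6 treated and 6 control arrays), with 1.25 in the set with no time stated and 0.61 at 72 h. Of 27 genes reported as targets of miR-221 and miR-222, 7 rose, 0 fell and 20 did not pass, and 9 rose and 1 fell when adjusted over the list alone. MYLIP, a ubiquitin ligase gene, rose by 0.46 ± 0.06, and HECTD2, another ubiquitin ligase gene, by 0.94 ± 0.15. HECTD2 turned to -0.24 with the median of its probe sets. The list shift did not pass with an estimated correlation (adjusted p = 0.262). Against the untreated arrays 13 members rose and 3 fell. Inflammatory genes of the NF-kappaB response fell in 7 of 13 cases and rose in 0, with 10 falls when adjusted over the list alone (adjusted p = 0.0320 with an estimated correlation). The chemokine genes CXCL1 and CXCL8 measured -1.90 ± 0.39 and -1.23 ± 0.11, the cytokine gene IL6 -0.94 ± 0.10 and NFKBIA, which encodes an NF-kappaB inhibitor, -0.40 ± 0.08, or -0.20 with the median of its probe sets. Against the untreated arrays these genes were not lower in the inhibitor arm, with CXCL1 at 1.14 ± 0.39, CXCL8 at 0.49 ± 0.11 and IL6 at 0.69 ± 0.10, and 11 of the 13 rose. Genes of the ATF4 and unfolded protein response rose in 8 of 23 cases, or 11 when adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). ATF3 and DDIT3, which encode stress-induced transcription factors, rose by 1.03 ± 0.16 and 0.51 ± 0.06. Against the untreated arrays 13 genes of the list rose and 2 fell.

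Of the genes listed as repressed by estrogen, 4 of 10 rose with the inhibitor, also when adjusted over the list alone (adjusted p = 0.0432 with an estimated correlation). Among them were EFNA1 at 0.63 ± 0.07 and BMF, a gene of cell death, at 0.64 ± 0.11. BMF rose less at 72 h than with no time stated, by a difference of -1.04 ± 0.22 (adjusted p = 0.0440 in limma). This list was not counted against the untreated arrays. The largest rises were those of SEL1L3 at 1.75 ± 0.13, the immediate early gene FOS at 1.67 ± 0.28, SORBS2 at 1.40 ± 0.29, ZBTB37 at 1.29 ± 0.21, DPY19L3 at 1.28 ± 0.11 and TMCO4 at 1.27 ± 0.17. DPY19L3 measured only 0.19 ± 0.11 against the untreated arrays (adjusted p = 0.188), because the control arm had lowered it by 1.09. Falls were ranked among called genes whose inhibitor arrays all lay below their controls in each set. After the inflammatory genes, the largest of these falls were those of CDC25A, a cell cycle phosphatase gene, at -0.84 ± 0.19, the ligand gene WNT7B at -0.79 ± 0.13 and TENT5B at -0.77 ± 0.19. CDC25A measured -0.33 and did not pass with the median of its probe sets, where WNT7B measured -0.35, and TENT5B did not pass without the filter on low values. TRPS1 measured 0.53 ± 0.19 (adjusted p = 0.12). In the limma fit, 683 of 10754 genes changed, 467 higher and 216 lower, and 23 changed at least 2-fold. In the set with no time stated 663 genes passed, or 200 when only the groups compared entered the fit, and at 72 h 212 passed, or 332 after quantile normalization. Without replicate 3 of the control arm at 72 h, 451 genes passed over both sets and 85 at 72 h.

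The mimic and inhibitor arms came from different lines with their own controls, and the comparison asks whether their changes run in opposite directions. Of 9998 genes tested in both, 212 fell with the mimic and rose with the inhibitor, where 64.2 would be shared by chance, and 19 rose with the mimic and fell with the inhibitor, against 9.07. Fewer genes moved the same way, with 5 higher in both and 20 lower in both, against 20.1 and 29. PRUNE1, a phosphodiesterase gene, measured -1.19 ± 0.05 with the mimic and 1.14 ± 0.07 with the inhibitor. FILIP1L measured -1.03 ± 0.14 and 1.01 ± 0.11, DPY19L3 -1.01 ± 0.08 and 1.28 ± 0.11, and ZBTB37 -1.07 ± 0.19 and 1.29 ± 0.21, with ZBTB37 at -0.62 with the mimic against the siRNA control arrays. HECTD2 measured -1.11 ± 0.10 and 0.94 ± 0.15, and CDKN1B -0.86 ± 0.06 and 0.93 ± 0.06. Across genes, which are not independent replicates, Pearson's r of the log2 differences was -0.257 and Spearman's rho -0.232. With the median of probe sets, 144 genes moved in opposite directions, and PRUNE1 measured 0.67 with the inhibitor. Of the 212 genes, 156 were lower with the mimic against untreated MCF7 arrays, 148 were higher with the inhibitor against untreated MB231 arrays, and 108 were both. With the inhibitor against untreated arrays PRUNE1 measured 1.17, but DPY19L3 0.19 and FILIP1L -0.28, and neither of these passed. The mimic and ESR1 siRNA arms shared 423 falls, against 244 by chance, and 152 rises, against 97.6. They also had 402 genes lower with the mimic and higher with the siRNA, against 316, and 96 the other way, against 75.3. Across genes, Pearson's r was 0.161 and Spearman's rho -0.0108, which differ in sign.

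**Figure D2:**
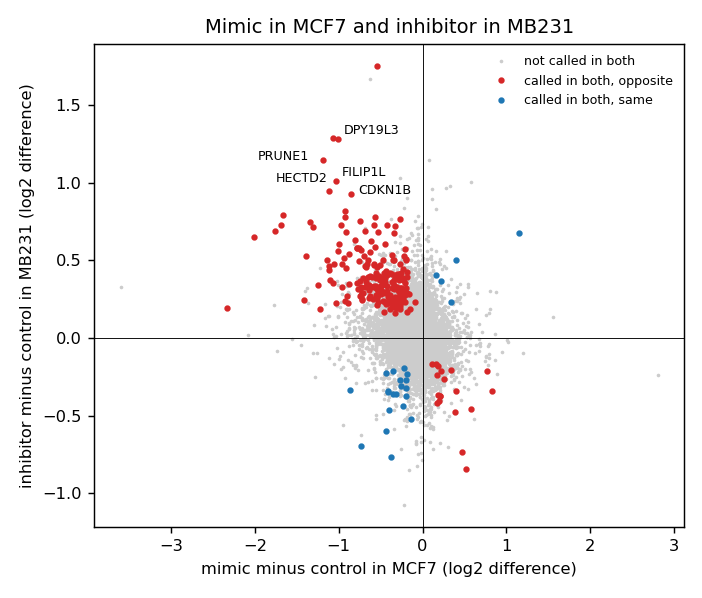
Log2 difference with the mimic in MCF7 (x axis) and with the inhibitor in MB231 (y axis) for each gene tested in both lines, with red points for genes that passed in opposite directions, blue for the same direction and grey for the others. The upper left holds 212 red points, among them PRUNE1, DPY19L3, FILIP1L, HECTD2 and CDKN1B.

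Control arms were compared with untreated cells of the same line to show what the control treatment itself did. HMOX1, which encodes the stress enzyme heme oxygenase, rose most in both lines, by 3.60 ± 0.07 in MCF7 and 3.66 ± 0.17 in MB231. Its rise was 5.58 and 6.18 in the set with no time stated and 1.63 and 1.13 at 72 h. In MCF7, genes of DNA replication and G1/S fell in 18 of 27 cases, or 21 when adjusted over the list alone, with GINS2, a replication complex gene, at -0.38 ± 0.04. Mitotic genes fell in 13 of 28 cases, or 17 when adjusted over the list alone (adjusted p = 0.0571 with an estimated correlation). Genes of the ATF4 response rose in 15 of 25 cases and fell in 1, with 16 rises and 1 fall when adjusted over the list alone, and ATF3 rose by 1.40 ± 0.15. Genes of hypoxia rose in 15 of 22 cases, also when adjusted over the list alone, with BHLHE40, a transcription factor gene, at 0.97 ± 0.10, or 0.60 with the median of its probe sets. The G1/S, ATF4 and hypoxia shifts passed with an estimated correlation, at adjusted p = 0.00295, 0.0432 and 0.0320. ESR1 measured 0.02 ± 0.08 in MCF7 (adjusted p = 0.88). In MB231, inflammatory genes rose in 12 of 13 cases, or 13 when adjusted over the list alone (adjusted p = 0.0280 with an estimated correlation), with CXCL1 at 3.05 ± 0.39, CXCL3 at 2.26 ± 0.15, CXCL8 at 1.72 ± 0.11 and IL6 at 1.64 ± 0.10. Interferon response genes rose in 22 of 25 cases, also when adjusted over the list alone (adjusted p = 0.0502 with an estimated correlation). IFIT3, an antiviral gene, rose by 2.16 in the set with no time stated and measured -0.00 at 72 h. In the limma fits 1358 of 10839 genes changed in MCF7, 857 higher and 501 lower, and 3190 of 10754 in MB231, 1781 higher and 1409 lower. In the set with no time stated and at 72 h, 447 and 1500 genes changed in MCF7, and 3835 and 569 in MB231. Without replicate 2 of the control arm at 72 h, 892 genes passed in MCF7, and without the filter on low values 11365 passed in MB231, mostly by small falls at background level. In the set with no time stated the 3′ minus 5′ difference of ACTB was higher in the control than in the untreated arrays, at 1.58 to 1.69 against 1.21 to 1.44 in MB231 and 1.27 to 1.40 against 1.18 to 1.26 in MCF7. At 72 h these ranges overlapped in both lines, and the effect was not tested.

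Untreated MB231 and MCF7 cells differed in genes of epithelial and mesenchymal identity and of the estrogen response. Epithelial junction genes were lower in MB231 in 20 of 21 cases and higher in 1, also when adjusted over the list alone, with CDH1, which encodes E-cadherin, at -11.86 ± 0.05 (SE, 6 arrays per line). Luminal markers were lower in 16 of 17 cases, also when adjusted over the list alone, with the transcription factor genes FOXA1 at -8.66 ± 0.07 and GATA3 at -5.24 ± 0.06. Mesenchymal markers were higher in 18 of 19 cases, also when adjusted over the list alone (adjusted p = 0.0571 with an estimated correlation), with VIM, which encodes vimentin, at 11.45 ± 0.05 and the receptor kinase gene AXL at 10.83 ± 0.06. Genes listed as induced by estrogen were lower in 29 of 33 cases and higher in 3, also when adjusted over the list alone (adjusted p = 0.0770 with an estimated correlation), with GREB1 at -9.51 ± 0.06 and TFF1 at -10.79 ± 0.22. ESR1 measured -9.80 ± 0.12. Under the median of probe sets ESR1 measured -1.47 and VIM 7.14. The epithelial and luminal shifts passed with an estimated correlation, at adjusted p = 0.0224 and 0.0410. The largest differences were those of IGFBP7, an insulin-like growth factor binding protein gene, at 11.68 ± 0.07, and of the long noncoding RNA DSCAM-AS1 at -12.05 ± 0.05. In the limma fit 9316 of 11098 genes differed, 4396 higher and 4920 lower in MB231. Differences of this size reach the background of the arrays in the lower line, so they depend on where that background lies.

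Among 7 lines with 2 or 3 panel arrays each, 16 arrays in all, the limma F test found 10270 of 12152 genes to differ between lines. The 10 genes with the largest spread between lines were DSCAM-AS1, LDHB, TFF1, KRT19, IGFBP5, VIM, CEP15, PLS3, GPX1 and GSTP1. DSCAM-AS1 averaged 14.47 in BT474EI and 14.10 in KPL1, and 2.17 in CAL51, 2.17 in MCF10A and 2.16 in MDA435. VIM averaged 14.91 in MDA435, 13.22 in MCF10A and 13.08 in CAL51, against 2.85 in KPL1. Epithelial junction genes passed in 21 of 21 cases, mitotic genes in 28 of 28 and genes listed as induced by estrogen in 33 of 35. Genes of the ERBB2 amplicon, the chromosome 17 region copied in HER2 positive cells, passed in 0 of 12 cases. The 3 arrays labelled BT474 did not share an ERBB2 level, at 14.65 in replicate 1, 9.60 in replicate 2 and 8.90 in replicate 3. The array labelled BT474.tb had 14.53 and MCF7 9.13. The spread of the BT474 arrays, with an SD of 3.14 for ERBB2 and 3.47 for GRB7, enters the F test. The 0 of 12 therefore does not show that amplicon genes were alike between lines. ERBB2 averaged 7.14 in MDA435 and 11.00 in BT474EI, with SDs of 0.11 and 0.01.

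BT474EI is an unexplained label, and its arrays were compared with the 3 arrays labelled BT474. Of these, replicates 2 and 3 lay nearer to MCF7 for 94.7% and 97.5% of 319 probe sets that separate BT474 from MCF7 and KPL1, so the differences below describe these 3 arrays and not BT474 as a line. Genes of DNA replication and G1/S were lower in BT474EI in 27 of 27 cases, with UHRF1, a DNA methylation cofactor gene, at -5.08 ± 0.15 (SE, 3 arrays per group). Mitotic genes were lower in 28 of 28 cases, with FOXM1, a mitotic transcription factor gene, at -6.02 ± 0.34. Genes of hypoxia and glycolysis were higher in 21 of 23 cases, with the glycolytic enzyme genes ALDOC at 5.60 ± 0.27 and ENO2 at 5.31 ± 0.28 and the angiogenic factor gene VEGFA at 2.32 ± 0.16. These 3 counts were the same when adjusted over the list alone, but the shifts did not pass with an estimated correlation, at adjusted p = 0.158, 0.348 and 0.0571. WDR72, ANGPTL4 and MYLK showed the largest rises, at 9.68 ± 0.14, 9.63 ± 0.15 and 9.45 ± 0.31, and ACKR3 and CYBA the largest falls, at -8.17 ± 1.08 and -8.08 ± 0.88. With the median of probe sets WDR72 measured 3.72, MYLK 2.31 and CYBA -4.03. ESR1 measured -0.17 ± 0.58 (adjusted p = 0.86), and 1.15 against BT474 replicate 1 alone. In the limma fit 3322 of 10447 genes differed, 1253 higher and 2069 lower, where the median of all genes was -0.14. Against BT474 replicate 1 alone, an arm of 1 array where only the BT474EI arrays give the spread, 6504 genes passed, and 1925 passed with a replicate block.

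The panel was described over 47 lines, after 9 labels that repeat or vary another label were left out. ESR1 lay above a log2 level of 8 in 16 lines and below 4 in 26, with the highest level of 12.62 in HCC1500. PGR lay above 8 in 11 lines, with 13.57 in T47D. BT474 entered the panel as the mean of its 3 arrays, which did not share their levels. Its PGR was 13.64 in replicate 1, 8.20 in replicate 2 and 9.60 in replicate 3. ERBB2 ranged from 6.48 in SW527 to 14.91 in HCC1954. CDH1 lay above 8 in 39 lines and below 4 in 8, and VIM reached 14.96 in HS578T. EGFR, which encodes the epidermal growth factor receptor, reached 13.91 in MDA468, and KRT5, a basal keratin gene, lay above 8 in 13 lines. The pigment cell genes MLANA and PMEL lay below 4 in all 47 lines, with highest levels of 2.88 and 2.12. Among the 7 lines with 2 or 3 arrays, all 8 measured genes of the pigment cell list differed, with a median SD between lines of 2.79. This does not set the list apart, since 84.5% of all genes differed in that test. The epithelial junction, basal and luminal lists had larger median SDs, of 3.61, 3.46 and 3.21.

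Relations between genes across these lines were computed for 16 pairs or clusters of lines, each with a two-sided permutation test. ESR1 rose with GATA3, a luminal transcription factor gene, at Pearson's r = 0.690 and Spearman's rho = 0.782, and with TRPS1 at r = 0.429 and rho = 0.424. For ESR1 and GATA3 the permutation p was 1e-05, the smallest the permutations can give, for both measures, with adjusted values of 2.67e-05 and 2.29e-05. For ESR1 and TRPS1 the permutation p was 0.00244 and 0.0032, with adjusted values of 0.00434 and 0.00569. ESR1 lay below a log2 level of 4 in 26 of the 47 lines. In these relations r may thus mostly contrast those lines with the others, and rho ranks many background values. GATA3 and FOXA1 gave r = 0.501 and rho = 0.621, with adjusted permutation values of 0.00068 and 2.29e-05. ERBB2 rose with its chromosome neighbours GRB7, at r = 0.878 and rho = 0.775, and STARD3, at r = 0.768 and rho = 0.703. CAV1 and CAV2 gave r = 0.912 and rho = 0.921, EGFR and CAV1 r = 0.688 and rho = 0.705, and the keratin genes KRT8 and KRT18 r = 0.902 and rho = 0.930 in the 42 lines with high KRT8. These 5 relations each had the smallest permutation p of 1e-05 for both measures. Without AU565, KPL1 and MDA435 the lines split by CAV1 level. CAV1 and CAV2 then gave r = 0.876 in the 24 lines with high CAV1 and 0.474 in the 20 with low CAV1, where it did not pass (adjusted p = 0.0540). EGFR and CAV1 gave r = 0.515 in the former and turned to -0.117 in the latter (adjusted p = 0.705). Without the 2 lines farthest from the median of the first gene, r was 0.672 for ESR1 and GATA3, 0.419 for ESR1 and TRPS1, 0.596 for GATA3 and FOXA1, 0.860 and 0.728 for ERBB2 with GRB7 and STARD3, 0.924 for CAV1 and CAV2, 0.671 for EGFR and CAV1 and 0.873 for KRT8 and KRT18.

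CDH1 split the lines into 39 with high and 8 with low levels. In the 39 lines with high CDH1, ZEB1, a repressor of CDH1, was lower where CDH1 was higher, at r = -0.667 and rho = -0.543 (permutation p = 0.00014 and 0.00046, adjusted 0.00032 and 0.00092), and r was -0.654 without the 2 farthest lines. ZEB1 lay below a log2 level of 4 in 37 of the 47 lines, so r rests on few lines and rho ranks many background values among these 39 lines. VIM gave r = -0.331 and rho = -0.278 there (permutation p = 0.0381 and 0.0874), which did not pass after adjustment at 0.0609 and 0.127. In the 8 lines with low CDH1 neither relation passed, with r = 0.122 for VIM and 0.211 for ZEB1 (exact permutation p = 0.942 and 0.740). ESR1 and PGR gave r = 0.288 in the 13 lines with high PGR and 0.336 in the 34 with low PGR (permutation p = 0.327 and 0.0536). KRT5 and KRT14, the basal keratin pair, gave r = -0.0992 and rho = 0.403 in the 34 lines with low KRT5, which differ in sign, with permutation p = 0.266 and 0.0197 and adjusted values of 0.355 and 0.0316. KRT5 lay below 4 in these lines, and rho was 0.00183 after quantile normalization and -0.0258 after median centring, where it did not pass. In the 13 lines with high KRT5 r was 0.0887 (permutation p = 0.769). The panel labels give no batch or date, so relations within batches could not be computed.

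**Figure D3:**
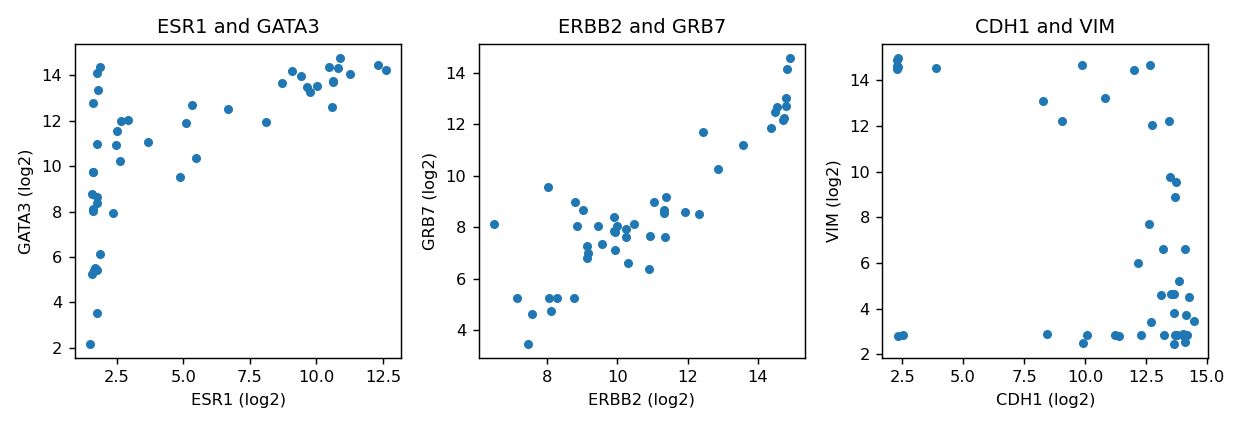
Log2 levels of pairs of genes across 47 lines, one point per line, with ESR1 against GATA3, ERBB2 against GRB7 and CDH1 against VIM. BT474 is plotted at the mean of its 3 arrays, with ERBB2 at 11.05, against 14.65 in replicate 1. GATA3 and GRB7 rise with their partners (r = 0.690 and 0.878), and CDH1 splits the lines into 39 with high and 8 with low levels. ESR1 lies below a log2 level of 4 in 26 of the lines.

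**Figure D4:**
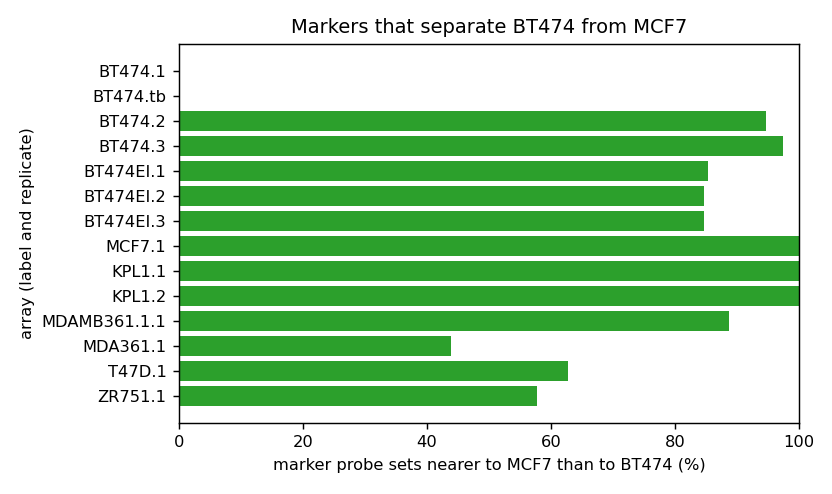
Percent of 319 probe sets that separate BT474 (replicate 1 and BT474.tb) from MCF7 and KPL1 whose log2 level lay nearer to the MCF7 side, one bar per array. The bars of BT474 replicates 2 and 3 reach 94.7% and 97.5%, against 62.7% in T47D and 57.7% in ZR751. Replicate 1 is at 0% because it was used to choose the probe sets.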

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

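All tests of explanations in this part, the counts of other splits among them, were chosen only after the result was seen, except the test on the genes outside the inflammatory and interferon lists that the control arm raised, which gave -0.15.

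The effects of the treatments differed between the 72 h set and the set with no time stated, by a test of the difference itself. The difference passed for 2936 genes with ESR1 siRNA, 890 with the mimic and 87 with the inhibitor. By its probe set with the highest mean, ESR1 itself fell less at 72 h, by a difference of 0.49 ± 0.16 (adjusted p = 0.0253 in limma). Other ESR1 probe sets, with lower means, went both ways. The probe set next in mean measured -1.73 with no time stated and -2.12 at 72 h. Of those below it, some measured more at 72 h, as with -1.12 and -2.37, and some less, as with -0.38 and -0.20. For these probe sets the difference between sets was not tested. Of the 12 largest changes over both sets, the difference passed for 8 with ESR1 siRNA, 5 with the mimic and 1 with the inhibitor. With ESR1 siRNA, TNS3 differed by 5.22 ± 0.50, VAT1L by 4.51 ± 0.81 and RAMP3 by -2.40 ± 0.33. With the mimic, ANXA1 differed by -3.77 ± 0.25, RUBCNL by -3.12 ± 0.33 and CYP26B1 by -2.34 ± 0.53. With the inhibitor, SEL1L3 differed by -2.19 ± 0.27. The set and the time cannot be told apart, because each time was run in 1 set, and the sets may also differ in batch or in dose (with the mean effect over both sets removed, 1 of 100 splits, the real one, gave the mimic's 890 genes).

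The control arms of the 2 lines differed from their untreated cells in different ways. The labels do not say whether both lines received the same control reagent or dose, so line and reagent cannot be told apart. The effect of the control arm over untreated cells differed between the lines for 2283 of 11311 genes, 1136 higher and 1147 lower in MB231. Among these were 9 of 13 inflammatory genes and 15 of 28 interferon response genes. The difference, MB231 minus MCF7, was 3.06 ± 0.35 for CXCL1, 1.74 ± 0.11 for CXCL8 and 1.64 ± 0.11 for IL6, and 1.66 ± 0.16 for the antiviral gene MX1.

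More genes fell than rose with the mimic in MCF7, 1699 against 524. Scaling between arrays may account for part of this, since 52.7% of the changed genes were rises after quantile normalization, against 23.6% as deposited, but median centring went the other way, with 19.7%. The control arm may account for another part, since against the siRNA control arrays 47.3% were rises. Genes lowered by the mimic itself remain likely as well: among genes changed at least 2-fold, falls made up 80% after quantile normalization and 63.2% against the siRNA control arrays, against 86.7% as deposited. The 3 explanations stay open together, and how much each gives was not tested.

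Inflammatory genes fell with the inhibitor in MB231, where the control arm had raised them. The 9 members raised at least 2-fold by the control, by a median of 1.64, were all lower in the inhibitor arm, with a median of -0.57, and their median over untreated cells was 0.89. A weaker response to transfection as a whole in the inhibitor arm might give this. The 83 other genes raised at least 2-fold had a median of -0.15, with 59 lower, which lies too near the bound set for this test to decide. The 8 interferon genes, which that test left out, had a median of -0.20, with 8 lower and 1 of them called. All these genes were chosen for high values in the control arrays, which also enter the inhibitor difference. Part of each fall may therefore come from the choice itself. Whether every raised gene lost the same share was tested in 3 forms, which gave different answers, so a general loss and a loss specific to inflammatory genes cannot be told apart.

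In these forms the inflammatory genes and the others lost these shares of the control rise. With rise and loss from the same control arrays, the shares were 32.7% ± 6.34 for 9 genes and 9.89% ± 2.88 for 83. With genes raised in both sets, and rise and loss from different sets, they were 38.6% ± 10.3 for 3 genes and 25% ± 7.96 for 13. With genes raised in either set and the loss from the other set, they were 32.6% ± 6.30 for 10 genes and -0.14% ± 1.16 for 330. The first form shares control arrays between rise and loss, and in the last the other genes had barely risen in the set of the loss, by a median of 0.14 against 0.83.

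A chance split of the arrays could be excluded where under 5% of 100 splits of the same arrays gave as many genes. Only 1 of 100, the real split, did so in each of the comparisons below. The labels do not say whether the arrays were separate cultures, so chance differences between cultures are not excluded. ESR1 siRNA gave 3577 genes, with at most 3115 in another split, the mimic 2223, with at most 2106, and the inhibitor 683, with at most 113. Control against untreated gave 1358 in MCF7, with at most 403, and 3190 in MB231, with at most 2099, and the 2 lines gave 9316, with at most 5167. The large counts in other splits point to a structure of the arrays, since a split that keeps the real arms of 1 set still calls that set's genes. For the difference between sets these splits decide nothing, since swapping the arms of 1 set turns the mean effect into the difference. There 10 of 100 gave as many genes as the mimic's 890, with at most 2223, and 4 of 100 as many as the inhibitor's 87, with at most 683. With the mean effect over both sets removed first, 1 of 100, the real split, gave as many in each, with at most 6 and 2 genes in another split. This removal leaves no difference when the arms of 1 set are swapped, so that split is no rival here. The other splits exclude only a chance split of these arrays.

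Within a single set, the splits are too few for a share under 0.05. There, 1 of 10 splits, the real one, gave the highest count each time. ESR1 siRNA at 72 h gave 4317 genes, with at most 4 in another split, and the mimic 168 with no time stated and 2709 at 72 h, with at most 2 in each. The inhibitor gave 663 with no time stated and 212 at 72 h, with at most 4 and 0, and BT474EI against BT474 gave 3322, with at most 0.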

How the results depend on the processing

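The exchange of the control arms in MCF7, BT474 from replicate 1 alone and the 7 lines without the BT474 arrays, alone or with BT474EI, were chosen after seeing the data, and the other alternatives were planned. Of the counts of genes, 249 of 281 alternative values lay within 1.5 times the value reported, and 32 did not. Of the named gene values, 9736 of 10225 kept their direction and side of the threshold, 473 no longer passed, 1 newly passed and 15 reversed. Of the gene list shifts, 328 of 428 kept their call, and 86 of the 100 that lost it did so with the estimated correlation. Of the relations across lines, 75 of 77 kept their call by Pearson's r, and with label variants kept ESR1 and PGR in lines with low PGR (0.39) and CDH1 and VIM in lines with high CDH1 (-0.37) newly passed. By Spearman's rho 72 of 77 kept direction and call. KRT5 and KRT14 in lines with low KRT5 no longer passed after quantile normalization (0.0018) and reversed after median centring (-0.026). Of relations that never passed by rho, ESR1 and PGR in lines with high PGR reversed with BT474 from replicate 1 alone (-0.060), and CDH1 with VIM (0.029) and ZEB1 (0.086) in lines with low CDH1 without AU565, KPL1 and MDA435. These counts leave out 3 relations whose clusters changed. KRT8 and KRT18 formed a single cluster of 56 labels with label variants kept (r = 0.856) and passed. Without AU565, KPL1 and MDA435 the lines split by CAV1. In lines with high CAV1 the relations passed, with r = 0.876 for CAV1 and CAV2 and 0.515 for EGFR and CAV1. In lines with low CAV1 neither passed, at 0.474 and, turned in sign, -0.117. The cause was not tested for any change below unless stated.

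With only the groups compared in the fit, which leaves fewer arrays to estimate the spread, counts with no time stated were 266 for ESR1 siRNA, 36 for the mimic and 200 for the inhibitor. Under that setting 136 genes differed between sets with the inhibitor, against 87, and 161 did with quantile normalization and 154 with a trended robust prior. Quantile normalization gave 332 genes for the inhibitor at 72 h. The median of probe sets gave 432 for the inhibitor with no time stated and 144 genes opposite between mimic and inhibitor, and reversed PIP4K2B with the mimic (0.090), HECTD2 (-0.24) and CDK6 (-0.22) with the inhibitor and TP53INP1 in the MCF7 control (-0.0065). No filter gave 11365 genes for the MB231 control, because 7337 genes below the filter were called, 99.4% of them lower, at a median level of 2.50 and a median difference of -0.06. Against the siRNA control arrays RRM2 (-0.11), PCNA (-0.070), KIF2C (-0.046), CDK1 (-0.081), IRF9 (-0.021) and KLF9 (0.12) reversed with the mimic, and against the control arrays COL3A1 reversed with ESR1 siRNA (-0.16). Of 16 values from other ESR1 probe sets, 3 kept their call and 12 no longer passed, and a probe set near background reversed with ESR1 siRNA at 72 h (0.35).

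Same-numbered arrays did not as a rule deviate together (median r of their residuals -0.01 in MCF7, -0.02 in MB231 and -0.02 in BT474), so the numbers do not pair arrays. Some pairs of arrays did share deviations. In MCF7, 7 of 56 same-numbered and 17 of 112 other pairs had r over 0.1, and in MB231 3 of 18 and 4 of 36. What these pairs share was not tested. The replicate block gave 1925 genes for BT474EI against BT474. BT474 replicate 1 alone gave 6504 genes and an ESR1 difference of 1.15, but it is an arm of 1 array, where the spread comes from the BT474EI arrays alone.

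Leaving out each array in turn gave these ranges. The mimic with no time stated ranged from 93 (without mimic replicate 1) to 264 (without mimic replicate 3), with 103 without control replicate 1. The inhibitor over both sets ranged from 451 (without control replicate 3 at 72 h) to 626. With no time stated it ranged from 315 (without control replicate 3) to 556, with 391, 391 and 388 without inhibitor replicates 1, 2 and 3. At 72 h it ranged from 85 (without control replicate 3) to 128 (without inhibitor replicate 3), with 124 and 118 without control replicates 1 and 2 and 116 and 108 without inhibitor replicates 1 and 2. The MCF7 control ranged from 892 (without control replicate 2 at 72 h) to 1231, with 905 without control replicate 3 of the set with no time stated. BT474EI against BT474 ranged from 1417 (without BT474EI replicate 2) to 6332 (without BT474 replicate 1), with 1754 and 1435 without BT474EI replicates 1 and 3. ESR1 there ranged from -0.82 (without BT474 replicate 1) to 0.24 (without replicate 3), with 0.08 without replicate 2. RIGI with the mimic ranged from -0.80 (without mimic replicate 3 of the set with no time stated) to 0.018 (without control replicate 1 at 72 h).

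Scaling moved the share of rises among changed genes. With quantile normalization and median centring it was 52.7% and 19.7% for the mimic, against 23.6%. It was 34.2% and 11.3% with no time stated, against 11.9%, and 52.6% and 21.3% at 72 h, against 26.5%. It was 49.6% and 68.7% for the MCF7 control, against 63.1%, and 48.6% and 74.6% for the MB231 control, against 55.8%. For untreated MB231 against MCF7 the median of all genes was -0.05 as deposited and -0.10 with each scaling. Genes below a log2 value of 4 lie near background, so differences called there, as without the filter, need not be differences of mRNA level.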

Other observations

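The tests on the BT474 arrays and on microRNA targets were chosen only after the result was seen, and those on genes that follow ESR1 across lines and on a move towards MB231 were written before.

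Some microRNA targets moved in opposite directions with the mimic and the inhibitor. Of 25 reported targets of miR-221 and miR-222 tested in both lines, CDKN1B, HECTD2, MYLIP and RALGAPA1 fell with the mimic and rose with the inhibitor. These 4 make up 16% of the list, against 2.09% of the other genes (one-sided Fisher's exact p = 0.00175, adjusted 0.00701 over 4 microRNA lists). Of the reported targets of miR-200, 1 of 12 did so, QKI (adjusted exact p = 0.454), and of those of miR-34 and let-7 0 of 12 and 0 of 9. A mimic and an inhibitor of miR-221 or miR-222 is a candidate explanation, found and tested on the same data. HECTD2 depends on the probe set in the inhibitor arm, where the median of its probe sets gave -0.24, and MYLIP measured -0.06 against untreated cells with the mimic.

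Genes that fell with ESR1 siRNA in MCF7 did not as a set follow ESR1 across the panel more closely than genes that rose. Their mean correlation with ESR1 over 47 lines was 0.046, against 0.111 for genes that rose and 0.0297 for the others, and falling minus rising genes gave -0.0648 (permutation p = 0.028). With the mimic, falling genes had 0.111 and rising genes 0.0651 (permutation p = 0.018). ESR1 lay below a log2 level of 4 in 26 of the 47 lines, so these correlations may mostly contrast those lines with the others. The gene that followed ESR1 most closely was GREB1 at r = 0.874, followed by DCPH1 at 0.837, ABAT at 0.823, SIAH2 at 0.762 and PGR at 0.761. Single genes did both, since 5 of the 10 that followed ESR1 most closely fell with ESR1 siRNA, among them GREB1, ABAT, SIAH2 and PGR, and 1 rose, SCUBE2 (r = 0.739) by 0.26.

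A move of MCF7 towards the levels of MB231 in both directions, as the test required, was not seen with the mimic. Of the genes that fell, 896 were lower in MB231, where 783 would be shared by chance, a ratio of 1.14, and 600 were higher, against 605. Of the genes that rose, 183 were higher in MB231, against 181 by chance, and 248 were lower, against 235. Only the falling genes thus leaned towards MB231, and this lean was not tested by itself.

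The arrays labelled BT474 replicates 2 and 3 lay at the levels of MCF7. Of 319 probe sets that separate BT474 replicate 1 and BT474.tb from MCF7 and KPL1, at least 94.7% lay nearer to MCF7 in these 2 arrays, and at least 94.3% without the genes of the ERBB2 amplicon, which argues against a loss of the amplicon alone. The 184 probe sets high in BT474 had medians of 3.14 and 3.06 there, against 9.14 in replicate 1 and 2.89 in MCF7, which argues against a mixture with at least 10% BT474 cells. Mislabelled arrays or another line remain a likely explanation. The arrays labelled BT474EI lay nearer to MCF7 for 84.6% to 85.3% of these probe sets and MDAMB361.1 for 88.7%, against 43.9% in MDA361.

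Other pairs of labels that share a name differed as well. ERBB2 was 14.81 in the array labelled ZR75 and 11.32 in the one labelled ZR751, and 10.05 in MDAMB361.1 against 13.59 in MDA361.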
